A study of Homo sapiens with 16 samples.

How the data were processed

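The data were 16 one-colour (Cy3) Agilent microRNA arrays of total RNA from 8 Xp11 renal cell carcinomas and 8 matched normal kidney samples, with a patient number per pair in the labels. Per the labels' protocols, cores were taken from formalin-fixed, paraffin-embedded blocks in areas enriched for tumor cells. Per the file headers, the deposited scanner files give intensity values from Agilent Feature Extraction 10.7.3.1, with spatial detrending on, and probe mappings on hg19. The deposited gProcessedSignal is a background-subtracted intensity that was not normalized between arrays. The deposited gMeanSignal and gBGMedianSignal are raw intensities, and gTotalGeneSignal is the sum over a microRNA's probes, per the file headers. The submitters' processing notes also name RMA, without its role. The authors' deposited value table holds log2 values for 2030 rows, of which 2006 are human microRNAs and 3 are empty. Its columns had medians of 3.14 to 3.21 and correlated across microRNAs with the same array's raw signal, taken as log2 of the median gMeanSignal over a microRNA's spots, with r of 0.963 to 0.994, so scale and direction are those of log2 signal; its background and normalization steps are not given in the sources used here.

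Each array held 60180 spots of human microRNA probes (4774 probes) and 2164 control spots, which were left out. Outlier-flagged spots were left out, the mean of the other spots was taken per probe, and the mean of a microRNA's probes gave its signal. Signals were divided by the array's 75th percentile over the 514 microRNAs detected on all 16 arrays, floored at the 5th percentile of scaled signals of detected microRNAs (-5.84 on the log2 scale), and log2-transformed. A fold change of a microRNA near the floor is understated. No spot was saturated. 1 array, the tumor array of pair 4, was marked by Feature Extraction as outside its quality range, and it was kept. Detection is the Feature Extraction call. The 869 microRNAs detected on at least 4 arrays were tested.

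Tests used R 4.3.3 and limma 3.58.1. Files were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. The main test was lmFit and eBayes on log2 values, tumor minus normal, with patient as a block and Benjamini-Hochberg adjusted p under 0.05. 9 microRNAs were at the floor on every array and were kept among those tested. Gene set tests of the 22 lists with at least 3 tested members used camera with a preset correlation of 0.01, and beside it camera with an estimated correlation and fry; 2 of 24 lists were too small. Array names match a list's name exactly or without its arm suffix. The lists leave out some tested microRNAs of a family or cluster, such as hsa-miR-34a-3p and hsa-miR-183-3p, and counts of members refer to the lists. Arm differences were log2 of the 5p arm minus log2 of the 3p arm. Per-array measures and spread were tested with exact permutations over all within-pair swaps. The lists, tests, the naming rule and most alternatives were chosen before the data were examined. The rule for named microRNAs took, among those past the threshold with the same sign in at least 7 of 8 pairs, the 12 largest rises and the 12 largest falls, then the members of the study-description list, up to 4 members with the smallest adjusted p of other lists described, and the 5 smallest adjusted p for arms. Of those other lists at most 3 members were taken where camera called the list and at most 2 otherwise, a limit set after the data were seen.

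The patient numbers pair the samples, since the labels give each number to a tumor and a normal sample of one patient. As a check, deviations from group means of same-numbered samples correlated at a median of 0.284, against -0.0477 for differently numbered samples, and 7 of 8 pairs were over 0.1. The 2 slides each held both groups in 4 pairs. Arrays of one group were compared for repeats by the SD of their log2 differences over the 514 microRNAs detected everywhere. The closest 2 normal arrays had an SD of 0.278, far below the median of 1.04 between normal arrays. The closest 2 tumor arrays had 0.496, against a median of 0.934. In all 56 comparisons the SD was above the median of 0.0293 expected from spot noise. Spot noise leaves out labelling and hybridisation, so this does not exclude repeat arrays of one sample; each array was counted as its own sample because the labels give each its own patient number and tissue. The sources used here leave open whether pairs 7 and 8 are independent, and an alternative averaged them. On the first and second principal components, their normal arrays scored -25.3 and 5.99, and -25.8 and 6.33. Their tumor arrays scored 3.20 and -14.7, and -6.51 and -17.3. Normal arrays of pairs 4 and 6 were as near each other (13.4 and 10.2, and 13.7 and 10.9), so near scores do not settle the question. The p-values of the main limma fit weigh a mean within-pair difference against the spread of such differences over these pairs. Camera p-values set a list's members against the other microRNAs tested.

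The pipeline was tested on simulated data of 869 microRNAs with 200 changed by known folds. In the tumor against normal comparison it recovered 48% of 1.5-fold changes, 72% of 2-fold, 96% of 4-fold and 100% of 8-fold changes, with 3.66% of calls false. The simulated noise was independent between microRNAs and no floor was applied, unlike on the real arrays, so these rates need not hold there. Alternatives covered background correction, scaling, probe summary, floor, detection filter, the value table, the block, slides, array weights, eBayes options, treat at 1.5-fold and each pair left out. Chosen after seeing the data were leaving out pairs 3, 7 and 8, removing each array's trend on probe GC content, normexp with offset 0, leaving out microRNAs at the floor on more than 8 arrays and adding log2 array brightness (the 75th percentile signal) as a covariate.

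Coordinates are 1-based hg19 probe mappings from the files, which carry part of the microRNA. Of the 24 microRNAs named for size of change, 3 map to more than 1 place and have no position given. No reference genome was used.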

Results

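MicroRNA levels were measured in 8 Xp11 renal cell carcinomas and in matched normal kidney from the same 8 patients, so the study compared each tumor with its own normal tissue. Xp11 renal cell carcinoma is a kidney cancer defined by fusions of the TFE3 gene on the short arm of the X chromosome. RNA came from cores of formalin-fixed, paraffin-embedded tissue and was hybridised to 16 one-colour Agilent arrays carrying probes for 2006 human microRNAs. Between 604 and 862 microRNAs were detected per array, and 514 were detected on all 16. Tumor arrays detected 703 ± 83.8 microRNAs (mean ± SD, n = 8) and normal arrays 777 ± 70.5 (n = 8), a mean within-pair difference of -74.5 that did not pass an exact two-sided permutation test (p = 0.156, all swaps within pairs). The 75th percentile signal used for scaling was 639 ± 231 in tumors and 916 ± 176 in normal tissue, and was lower in the tumor in 6 of 8 pairs (exact two-sided permutation p = 0.0547). The number of arrays limits the precision of the values below, which are log2 signals relative to that percentile.

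Tumors carried more miR-34a-5p and miR-34b-5p, miR-221-3p and miR-222-3p, miR-21-5p, miR-185-5p and miR-15a-5p than their matched kidney, and miR-200c-3p and miR-141-3p were not detected in any tumor. Among rises measured in all 16 samples the largest was that of hsa-miR-34a-5p, a microRNA induced by p53, at 13.2-fold, from -1.83 ± 1.02 in normal tissue to 1.89 ± 0.92 in tumors (log2, mean ± SD, n = 8 each; limma adjusted p = 0.00082). hsa-miR-34b-5p, of the same family, rose 12.6-fold and was detected in 8 of 8 tumors and 4 of 8 normal samples, so its fold depends on the floor and is understated. hsa-miR-222-3p and hsa-miR-221-3p, neighbours on the X chromosome that repress the cell cycle inhibitor CDKN1B, rose 8.26-fold and 5.44-fold, each in 8 of 8 pairs. hsa-miR-21-5p, raised in many cancers, was 7.78-fold higher on average but only in 7 of 8 pairs, with a standard error of 0.69 on the log2 scale, and it passed in 18 of 32 alternatives (limma adjusted p from 0.00412 to 0.641). The pair in which hsa-miR-21-5p was lower was pair 4, and without it the log2 difference was 3.51 (limma adjusted p = 0.0143). Of 869 microRNAs tested, 37 were higher and 21 lower in tumors at a limma adjusted p under 0.05 with patient as a block. Of these, 32 were higher and 15 lower in all 8 pairs, an agreement that selection by a paired test favours.

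Other large rises were those of hsa-miR-1260a (6.25-fold), hsa-miR-185-5p (6.20-fold), hsa-miR-1260b (5.40-fold) and hsa-miR-342-3p (5.20-fold). hsa-miR-15a-5p and hsa-miR-16-5p, which share a seed sequence, rose 5.38-fold and 3.84-fold, and hsa-miR-148a-3p rose 4.77-fold. hsa-miR-16-5p and hsa-miR-148a-3p each passed in 22 of 32 alternatives. Among the falls, hsa-miR-4485 and hsa-miR-1973 were 3.16-fold and 3.15-fold lower, each in 8 of 8 pairs. hsa-miR-4531 was 3.04-fold lower. hsa-miR-10b-5p, which lies in the HOXD cluster, and hsa-miR-100-5p were 2.76-fold and 2.74-fold lower, each in 7 of 8 pairs, and passed in 18 and 19 of 32 alternatives. hsa-miR-664b-5p and hsa-miR-664a-5p fell 2.68-fold and 2.66-fold, and hsa-miR-4647, hsa-miR-127-3p and hsa-miR-4665-5p by 2.33-fold, 2.33-fold and 2.21-fold. hsa-miR-127-3p was detected in 2 of 8 tumors, so its fold is set by the floor, and it passed in 4 of 8 other scalings and 12 of 31 alternatives. hsa-miR-4647 passed in 16 of 32 alternatives and hsa-miR-4665-5p in 13 of 32. All 24 of these microRNAs moved in the same direction on both slides. The naming rule, which needs the same sign in at least 7 of 8 pairs, favours that agreement. By hg19 probe mappings in the files, hsa-miR-34a-5p lies on chromosome 1 at 9211750 to 9211769, hsa-miR-222-3p on chromosome X at 45606497 to 45606509 and hsa-miR-221-3p on chromosome X at 45605653 to 45605671. hsa-miR-185-5p lies on chromosome 22 at 20020681 to 20020697 and hsa-miR-21-5p on chromosome 17 at 57918636 to 57918655.

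**Figure D1:**
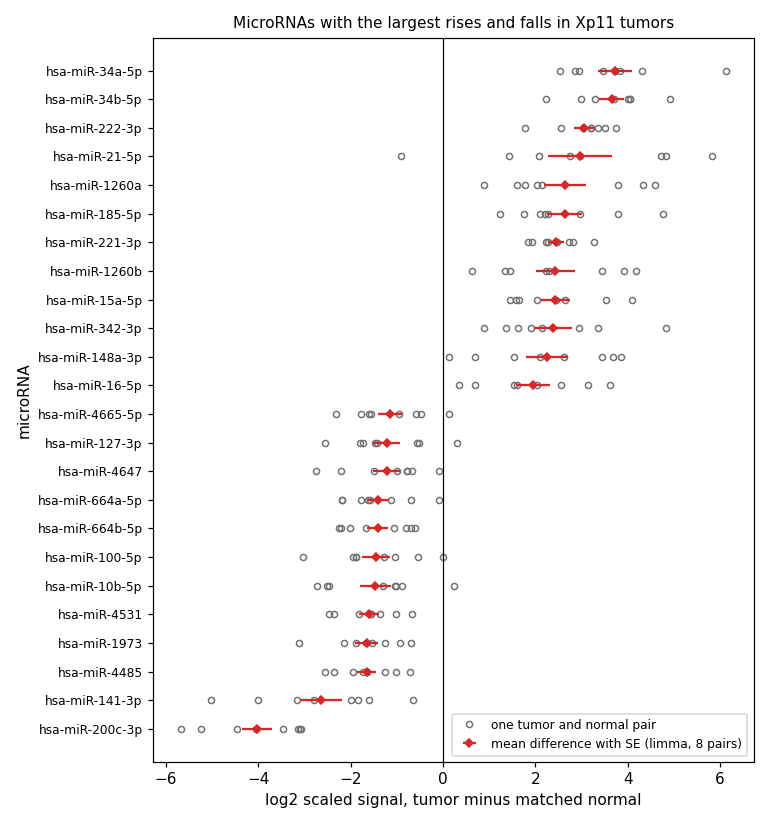
The x axis gives log2 scaled signal in the tumor minus that in its matched normal sample, and the y axis names the 12 microRNAs with the largest rises and the 12 with the largest falls. Open circles are the 8 pairs and diamonds the mean difference with its standard error; hsa-miR-34a-5p averages 3.72 and hsa-miR-200c-3p -4.03, the latter with tumors at the floor.

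The counts depended on which pairs entered. Without pair 7 there were 17 microRNAs higher and 8 lower, without pair 8 there were 20 and 9, without pair 1 there were 23 and 11, and without pair 4 there were 59 and 53. Averaging pairs 7 and 8, whose independence is open, gave 18 higher and 8 lower. In that fit 9 of the 12 named rises and 7 of the 12 named falls passed. The tumor array of pair 4 was the one marked by Feature Extraction as outside its quality range, with 7.64% of its spots outlier-flagged against 2.93% to 4.06% on the other arrays. Without pairs 3, 7 and 8, whose normal arrays stood apart from the rest, 13 were higher and 5 lower, and 7 of the 12 named rises and 3 of the 12 named falls passed. Within slide 1 (4 pairs) limma called 0 higher and 0 lower, with 85 at an unadjusted p under 0.05, and within slide 2 (4 pairs) it called 9 higher and 5 lower. The unpaired fit with slide as a block gave 34 higher and 16 lower. Normexp background correction with an offset of 50 moved the median of all changes from -0.15 to 0.29 on the log2 scale and gave 217 higher and 38 lower. With log2 array brightness as a covariate in the paired fit, 6 were higher and 3 lower, and 4 of the 12 named rises and 2 of the 12 named falls passed. Those rises were hsa-miR-34a-5p, hsa-miR-34b-5p, hsa-miR-222-3p and hsa-miR-221-3p, and those falls hsa-miR-200c-3p and hsa-miR-4485. hsa-miR-21-5p, hsa-miR-185-5p and hsa-miR-15a-5p did not pass (limma adjusted p = 0.262, 0.0521 and 0.0627). With this covariate the named rises kept 59.1% to 112% of their size and the named falls 72.3% to 134%.

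miR-200c-3p and miR-141-3p were detected in 8 of 8 normal samples and in 0 of 8 tumors. These microRNAs of the miR-200 family repress ZEB1 and ZEB2 and are abundant in epithelial cells. Because no tumor array detected them, the tumor level is a bound, taken per array as the higher of the lowest signal among microRNAs well above background and the microRNA's own signal. In the main processing hsa-miR-200c-3p was at least 9.66-fold lower in tumors, and hsa-miR-141-3p at least 3.72-fold lower. Their limma adjusted p of 0.000239 and 0.0124 belong to the floored values, not to the bounds. For hsa-miR-200c-3p all 8 tumors were at the floor, so spread between tumors did not enter its test. Its measured log2 difference ranged from -5.95 to -1.74 across alternatives, and it passed in 30 of 31. hsa-miR-141-3p passed in 7 of 8 other scalings and 25 of 31 alternatives, with a measured log2 difference of -0.68 under normexp with an offset of 50 (adjusted p = 0.0881). With array brightness as a covariate its measured log2 difference was -3.20 (standard error 0.60, limma adjusted p = 0.0603), against -2.64 (0.46) without. Of 7 tested family members, 3 fell and 4 did not pass the test, and 6 fell when adjusted over the list alone. hsa-miR-200b-5p fell 1.63-fold, and hsa-miR-429 had a log2 difference of -1.76 with an adjusted p of 0.0781. The family's median log2 difference was -1.41, and camera with a preset correlation called it lower (adjusted p = 0.000496), a call lost with an estimated correlation (adjusted p = 0.266 with an estimated correlation). By fry the family's adjusted p was 0.00104 for a one-way fall. With normexp and an offset of 50, hsa-miR-200b-5p changed sign, to 0.11.

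Of the 8 kidney-enriched microRNAs, 1 fell, hsa-miR-10b-5p, and 7 did not pass, with 1 falling when adjusted over the list alone. hsa-miR-10a-5p had a log2 difference of -0.88 (adjusted p = 0.0941). hsa-miR-192-5p and hsa-miR-194-5p, abundant in renal tubules and chosen after their values were seen, had log2 differences of -2.20 with a standard error of 1.21 and -2.16 with a standard error of 1.11, so their spread between pairs was large. The list's median was -1.23 and camera did not call it (adjusted p = 0.155), though it was called lower in 3 of 8 other scalings and 8 of 32 alternatives, with adjusted p from 0.000308 to 0.555. fry gave an adjusted p of 0.0795 for a one-way fall and 0.0349 for change in either direction. On slide 1 the median was -1.59 and on slide 2 it was -0.56.

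The miR-221 and miR-222 cluster rose as a group: 3 of 3 tested members passed, over all microRNAs tested and adjusted over the list alone. Its median log2 difference was 2.44 (camera adjusted p = 2.02e-05), and 2.56 on slide 1 and 2.33 on slide 2. The camera adjusted p was 0.0726 with an estimated correlation, and fry gave 2.29e-05 for a one-way rise. hsa-miR-221-5p, the other arm of its precursor, rose 3.47-fold and was detected in 6 of 8 tumors and 2 of 8 normal samples, and it passed in 15 of 31 alternatives. In the miR-34 list, which leaves out hsa-miR-34a-3p, 2 of 3 tested members rose, also when adjusted over the list alone. The list's median was 3.65 (camera adjusted p = 0.00154, and 0.176 with an estimated correlation, fry adjusted p = 0.000111 for a one-way rise). The other 2 members of the list, hsa-miR-34b-3p and hsa-miR-34c-5p, were detected in 0 and 2 of 8 tumors and in 0 normal samples and were not tested, and with no detection filter the median was 0.10 over all 5. hsa-miR-34a-3p, not in the list, had a log2 difference of 0.82 (limma adjusted p = 0.0842) and was detected in 6 of 8 tumors and 0 normal samples. hsa-miR-34c-3p was at the floor in tumors and had a log2 difference of -0.01, whose sign changed with 4 of 8 other scalings.

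Among 12 tested members of the miR-17 to miR-92 clusters, which promote proliferation, 2 rose, and 8 rose when adjusted over the list alone. hsa-miR-106b-5p rose 3.56-fold and hsa-miR-25-3p 2.39-fold, passing in 18 and 19 of 32 alternatives. The list's median was 0.96 (camera adjusted p = 3.19e-05, and 0.277 with an estimated correlation, fry adjusted p = 0.0273 for a one-way rise). Of 9 let-7 members 0 passed limma's test over all microRNAs and 0 when adjusted over the list alone, with 4 at an unadjusted p under 0.05. The let-7 median was 0.59 and camera called the list higher (adjusted p = 0.0195, and 0.513 with an estimated correlation), while fry did not (adjusted p = 0.340 for a one-way rise). hsa-let-7i-5p had the smallest adjusted p of the family, 0.0588, with a log2 difference of 1.60. Without pairs 3, 7 and 8 the let-7 median was -0.11. The miR-29 list also had 0 of 6 members past the test over all microRNAs and 3 higher when adjusted over the list alone, the same number as at an unadjusted limma p under 0.05. Its median was 1.17 (camera adjusted p = 0.0157, and 0.377 with an estimated correlation, fry adjusted p = 0.0404 for a one-way rise), and hsa-miR-29c-3p had a log2 difference of 2.18 with an adjusted p of 0.0531. In the miR-148 and miR-152 list 1 of 3 rose, hsa-miR-148a-3p, and 2 when adjusted over the list alone (median 0.82, camera adjusted p = 0.0482, and 0.410 with an estimated correlation, fry adjusted p = 0.0877 for a one-way rise). That list was not called in the unpaired fit without the patient block (adjusted p = 0.0654), and neither it nor the miR-29 list was called without pairs 3, 7 and 8. Other scalings called the let-7 list in 5 of 8, the miR-29 list in 6 of 8 and the miR-148 and miR-152 list in 3 of 8, and with array brightness as a covariate camera called none of the 3 (adjusted p = 0.846, 0.275 and 0.241).

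Of 11 tested microRNAs reported raised in clear cell renal carcinoma, the commonest kidney cancer, 5 rose and 6 did not pass, and 7 rose when adjusted over the list alone. The 5 were hsa-miR-34a-5p, hsa-miR-222-3p, hsa-miR-21-5p, hsa-miR-185-5p and hsa-miR-221-3p. The 6 that did not pass, with their log2 differences, were hsa-miR-210 (1.03), hsa-miR-155-5p (0.37), hsa-miR-224-5p (1.29), hsa-miR-452-5p (-0.03), hsa-miR-142-3p (1.71) and hsa-miR-142-5p (0.46). The median was 1.71 (camera adjusted p = 2.61e-07, and 0.0726 with an estimated correlation, fry adjusted p = 0.000138 for a one-way rise). Of 13 reported lowered there, 2 fell, hsa-miR-200c-3p and hsa-miR-141-3p, and when adjusted over the list alone 6 fell and 1 rose. The median was -0.65 (camera adjusted p = 0.0237, and 0.368 with an estimated correlation, fry adjusted p = 0.00548 for a one-way fall), and 0.13 with normexp and an offset of 50. Both lists share members with the miR-200, miR-34 and miR-221 lists above. No clear cell or papillary tumors were analysed here.

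Of 6 tested microRNAs named in the study's description, 4 rose and 2 did not pass; the list was chosen on these samples and is not independent evidence. hsa-miR-221-3p, hsa-miR-185-5p, hsa-miR-148a-3p and hsa-miR-196b-5p were those that rose, and when adjusted over the list alone 4 rose and 1 fell. hsa-miR-196b-5p, from the HOXA cluster, rose 3.29-fold in 8 of 8 pairs (limma adjusted p = 0.000911). hsa-miR-133b had a log2 difference of -0.65 (adjusted p = 0.0974) and hsa-miR-658 one of -0.08 (adjusted p = 0.507), and the signs of both changed under normexp with an offset of 50. A further member, hsa-miR-642a-5p, was detected in 1 of 8 tumors and 0 of 8 normal samples and was not tested. The median was 1.99 (camera adjusted p = 0.00102, and 0.176 with an estimated correlation, fry adjusted p = 0.000234 for a one-way rise).

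**Figure D2:**
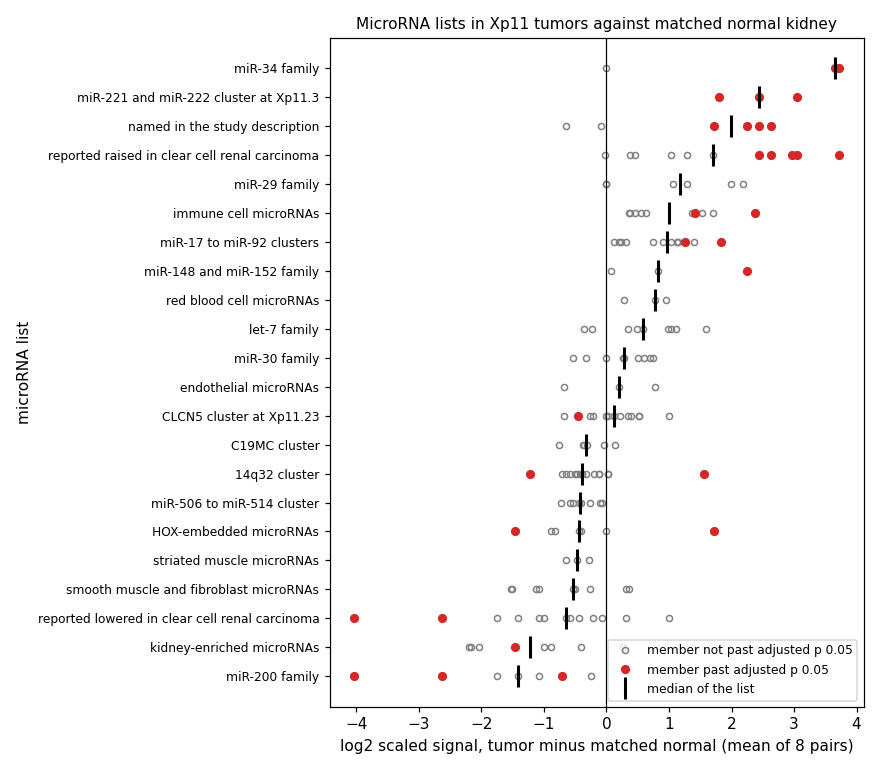
The x axis gives the mean log2 difference between tumors and matched normal samples over 8 pairs, and the y axis names the 22 lists with at least 3 tested members. Each circle is a microRNA, filled where its adjusted p over all 869 is under 0.05, and the bar is the list's median, from -1.41 in the miR-200 family to 3.65 in the miR-34 family.

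Among markers of other cell types in the tissue cores, camera with a preset correlation called the immune cell list higher in tumors, with a median of 1.00 and 2 of 10 members past limma's test (camera adjusted p = 0.000496). The call was lost with an estimated correlation (adjusted p = 0.350 with an estimated correlation), while fry gave an adjusted p of 0.0404 for a one-way rise. The 2 that rose were hsa-miR-342-3p (5.20-fold) and hsa-miR-146a-5p (2.68-fold), also when adjusted over the list alone, and the latter passed in 17 of 32 alternatives. The median was 0.39 without pairs 3, 7 and 8 (camera adjusted p = 0.0991) and 0.51 with array brightness as a covariate (camera adjusted p = 0.133). hsa-miR-142-3p, made in blood-forming cells, had a log2 difference of 1.71 with an adjusted p of 0.112. Camera did not call the endothelial list (adjusted p = 0.840), the smooth muscle and fibroblast list (adjusted p = 0.257), the striated muscle list (adjusted p = 0.181) or the red blood cell list (adjusted p = 0.240), and 0 members of these lists passed limma's test over all microRNAs, with 1, 1, 2 and 0 of them at an unadjusted p under 0.05. fry gave the striated muscle list an adjusted p of 0.0305 for a one-way fall, though its median of -0.48 changed sign in 2 of 8 other scalings, both with normexp, to as much as 0.26. Camera called that list lower in 2 of 29 alternatives and the red blood cell list higher in 1 of 30. Camera called the smooth muscle and fibroblast list lower in 4 of 32 alternatives (adjusted p from 3.4e-05 to 0.597), with a median of -1.38 without pairs 3, 7 and 8 and of -1.39 with array brightness as a covariate. Adjusted over the list alone, 1 endothelial microRNA fell. Of the list of neuronal and liver microRNAs 2 members were tested, and limma put 0 past the threshold and 0 at an unadjusted p under 0.05.

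HOX-embedded microRNAs went both ways: of 7, hsa-miR-196b-5p rose, hsa-miR-10b-5p fell and 5 did not pass, and adjusted over the list alone 1 rose and 3 fell. fry's test for change in either direction gave an adjusted p of 4.8e-05, while camera did not call the list (adjusted p = 0.464). In the imprinted cluster on the long arm of chromosome 14, hsa-miR-487b rose 2.95-fold and hsa-miR-127-3p fell, of 16 tested. hsa-miR-487b passed in 5 of 8 other scalings and 13 of 31 alternatives. Camera gave the cluster an adjusted p of 0.157 and called it lower in 4 of 32 alternatives, while fry gave an adjusted p of 0.0404 for a one-way fall and 0.00266 for change in either direction. The cluster's median was -0.39 and changed sign in 2 of 8 other scalings, both with normexp, to as much as 0.27. Of 13 members of the CLCN5 cluster, on the short arm of the X chromosome, 1 fell, hsa-miR-500a-5p, by 0.45 on the log2 scale, a call made in 0 of 8 other scalings and 3 of 32 alternatives (limma adjusted p from 0.0112 to 1). Camera gave the cluster an adjusted p of 0.492. Of the lists' members, none of the 9 of the miR-30 family, the 8 tested of the miR-506 to miR-514 cluster, the 6 tested of the C19MC cluster or the 1 tested of the miR-183, miR-96 and miR-182 cluster passed limma's test over all microRNAs or adjusted over the list alone, with 2, 2, 0 and 0 at an unadjusted p under 0.05. Camera did not call the first 3 of these lists (adjusted p = 0.157, 0.160 and 0.492), but called the miR-506 to miR-514 cluster lower in 3 of 32 alternatives (adjusted p from 0.00822 to 0.534). fry gave that cluster an adjusted p of 0.0404 for a one-way fall, and its median of -0.42 turned to 0.14 under normexp with an offset of 50. Camera called the miR-30 family higher in 1 of 32 alternatives.

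The difference between the 2 arms of a precursor passed the test for 11 of 114 precursors with both arms tested (limma adjusted p under 0.05, patient as a block). In 1 of the 11, hsa-miR-127, named after its values were seen, the 5p arm was at the floor on all 16 arrays, so its difference repeats the fall of the 3p arm and no balance was measured. In 7 of the 11 both arms were above the floor on every array. hsa-miR-34a had the smallest adjusted p, 0.00103, with the 5p arm gaining 2.90 over the 3p arm on the log2 scale, though the 3p arm was at the floor on 10 of 16 arrays and the size of the change is open. hsa-miR-21 gained 1.86 in favour of its 5p arm in 8 of 8 pairs. For hsa-miR-664a, hsa-miR-4665 and hsa-miR-664b the balance moved by -2.09, -1.94 and -1.87, toward the 3p arm, each in 8 of 8 pairs and with both arms above the floor on every array. The unpaired fit, with no patient block, called 3 precursors, and the paired fit with array brightness as a covariate called 1.

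Tumors did not differ detectably from normal samples in how much they varied: the median SD over tested microRNAs was 0.56 in tumors and 0.62 in normal samples, a difference of -0.07 (exact two-sided permutation p = 0.609, all swaps within pairs).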

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

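The tests of principal component 1, of the GC trend, of array brightness and of renal epithelium were chosen after the results they bear on were seen; those of other splits were planned. In each group of 8, a value was singled out where the gap to its nearest neighbour was a large share of the group's range, and chance does this in about 1 of 20 groups. Of 134 groups examined, 11 were singled out. Among tumors, the highest value stood apart for hsa-miR-185-5p (0.574 of the range), hsa-miR-206 (0.729), hsa-miR-96-5p (0.531), and for hsa-miR-141-3p, hsa-miR-658 and hsa-miR-9-5p (1 of the range, with the other tumors at the floor or tied). Among normal samples the lowest value stood apart for hsa-miR-4485 (0.62) and hsa-miR-1973 (0.784), and the highest for hsa-miR-34c-3p (1), hsa-miR-500a-5p (0.54) and hsa-miR-144-3p (0.594). hsa-miR-206 in tumors and hsa-miR-34c-3p in normal samples lay next to the floor, with log2 means of -5.83 and SDs of 0.015 and 0.019, so their gaps are tiny on the log2 scale.

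Chance is an unlikely source of the number of microRNAs called. Of 100 splits that swap tumor and normal within pairs, only the real one (1 of 100) called as many as 58. The highest other called 3. For arm differences chance is unlikely too, with 11 in the real split (1 of 100 as large) and 8 in the highest other. With 100 splits, 1 of 100 is the smallest share possible, so chance is not excluded for either count. The splits also swapped pairs 7 and 8 separately, and 6 arm differences were called with those pairs averaged. Chance stays open for the number of lists called. At least the real 11 were called in 8 of 100 splits, and the highest other gave 13. That is more than the real split, which points to microRNAs moving together across samples.

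The first principal component of the arrays held 44.6% of the variance and set 3 normal arrays apart from the rest. Slide explained 0.079% of its variance, which argues against a slide difference. The GC content of probes and group stay open as its source. Probe GC content may have a part, with rho of -0.39 between loadings and GC content over the tested microRNAs, which are not independent replicates. Tumors scored higher in 7 of 8 pairs, by 15.2 on average (exact two-sided permutation p = 0.0156), which is consistent with a part for group, and tumor against normal explained 24.02% of the variance.

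The 24 microRNAs named by size of change were weighed against technical trends. After each array's trend on GC content was removed, 24 of 24 still passed, which argues against that trend as the whole cause. Tumor arrays were dimmer in 6 of 8 pairs, and a part for brightness stays open: with brightness as a covariate 2 of 12 falls and 4 of 12 rises passed, with 72.3% to 134% of the falls and 59.1% to 112% of the rises kept. The least kept fall, hsa-miR-100-5p, went from -1.45 (standard error 0.31) to -1.05 (0.40), and the least kept rise, hsa-miR-1260b, from 2.43 (0.42) to 1.44 (0.32). The 24 were chosen for passing the paired test of tumor against normal tissue. Whether the tumor itself or a difference in tissue handling underlies their changes was not tested.

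hsa-miR-200c-3p and hsa-miR-141-3p were not detected in any tumor. Outside their family, the 95 microRNAs detected in all normal samples at a mean within 0.5 of that of hsa-miR-200c-3p (log2) had 100% of their tumor detection calls made, and the 102 like hsa-miR-141-3p had 98.7%, which argues against dimmer tumor arrays. A lower share of renal epithelial cells in tumor cores remains open. The 7 kidney-enriched microRNAs with room to fall as far had a median of -1.47 with an interquartile range of 1.17 over members, short of the bound of 3.27 for hsa-miR-200c-3p. Within pairs that bound exceeded the fall of the median member by 2.02 on average, in 6 of 8 pairs (exact two-sided permutation p = 0.0625), and the bound for hsa-miR-141-3p by 0.65, in 5 of 8 pairs (p = 0.477), so the spread between pairs leaves it undecided.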

How the results depend on the processing

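In the 32 alternatives the 12 named rises and 12 named falls, where tested, kept their direction. Chosen after seeing the data were leaving out pairs 3, 7 and 8, removing the GC trend, normexp with offset 0, leaving out microRNAs mostly at the floor and the brightness covariate. With no replicate block 33 were higher, 15 lower and 10 lists called, 43 of the 58 calls were shared, 9 of the 12 named falls passed, and arm differences went from 11 to 3, and to 3 with slide as a block too. Signal over background limits the microRNAs near the floor.

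Counts of higher and lower microRNAs (37 and 21) moved by over 1.5 times, the cause not tested unless given, as follows. The value table gave 59 and 43, the floor 4 times lower 58 and 38, and no detection filter 11 and 5 over 2006 microRNAs. Normexp with offset 50 gave 217 and 38 with 26 arm differences at a median change of 0.29, and offset 0 gave 69 and 22 at 0.11, against -0.15 without normexp, so the correction and the added constant each moved it. Array brightness as a covariate gave 6 and 3 with 1 arm difference. Lower counts alone moved with RMA-style values (36), the brightest probe (32), detection on at least 8 arrays (38), array weights (38, against 40 higher), the GC trend removed (46, against 52 higher) and without microRNAs at the floor on over 8 arrays (35). Among other sets of pairs, slide 1 gave 0 and 0 with 2 arm differences, slide 2 gave 9 and 5 with 3, pairs 7 and 8 averaged 18 and 8 with 6, and without pairs 3, 7 and 8 there were 13 and 5 with 5. Treat at 1.5-fold gave 8 and 3 with 3. Leaving out each pair in turn gave 17 to 59 higher, 8 to 53 lower, 9 to 11 lists and 5 to 12 arm differences. No detection filter gave 17 arm differences, and detection on all 16 arrays 6 lists. hsa-miR-200b-5p turned to 0.11 and hsa-miR-34c-3p to 0.46 with normexp at offset 50, and the let-7 list to -0.11 without pairs 3, 7 and 8; the cause was not tested. The detected count from spots well above background, at least 0.5 of them per microRNA, differed by -76.9 (exact permutation p = 0.125), and spread by -0.03 with RMA-style values and -0.09 over microRNAs detected on all 16 arrays, each on the same side of the threshold as before.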

Other observations

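The test in this part was chosen after the falls of miR-664a-5p, miR-664b-5p and miR-1291 were seen. Several called microRNAs fall outside the naming rule and are mentioned after their values were seen. hsa-miR-340-5p and hsa-miR-22-5p rose by 1.38 and 1.92 on the log2 scale, each in 8 of 8 pairs (limma adjusted p = 0.0124 and 0.0183). hsa-miR-484 had a log2 difference of 1.59 and hsa-miR-503-5p one of 1.02, both past the threshold and higher in 8 of 8 pairs. hsa-miR-342-5p, the partner arm of miR-342-3p, was 2.84-fold higher, in 8 of 8 pairs. Over all calls, 3 microRNAs called higher were detected on at most 2 normal arrays, and 5 called lower on at most 2 tumor arrays.

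The microRNA names hsa-miR-664a-5p, hsa-miR-664b-5p and hsa-miR-1291, which fell, are made from snoRNA precursors, and a hypothesis is that snoRNA fragments as a class may be lower in tumors. Of 4 further snoRNA-derived names tested, 0 fell past the threshold, and all 4 had positive log2 differences. They include hsa-miR-664a-3p and hsa-miR-664b-3p, from the same precursors as names that fell. The other names, hsa-miR-3651 and hsa-miR-3653, are too few to decide for the class, so the hypothesis stays open. hsa-miR-3651 had a log2 difference of 1.07 (limma adjusted p = 0.0588) and hsa-miR-3653 one of 0.20 (limma adjusted p = 0.539), and the 3p arms hsa-miR-664a-3p and hsa-miR-664b-3p had 0.68 and 0.45.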
